A study of Sus scrofa with 20 samples.

How the data were processed

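Kidney tissue of 20 pigs was profiled, 10 in the ND group and 10 in the control group, and each sample's group and animal number were taken from its title. Per the labels' protocols, total RNA was extracted with TRIzol, and 250 ng were made into biotin-labelled cRNA for 1-colour arrays. The labels describe 2 specimens per animal but give 1 array for each animal number, so each array was taken as 1 animal. The labels name no scan date or batch.

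The authors deposited 1 value per probe set and array. The log2 unit of the deposited values was inferred from their narrow range, 0.88 to 16.2, and was not stated. The method of background correction, summarization and normalization between arrays is not given in the sources used here. It can move the balance between rises and falls, since array quartiles were close but not identical.

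The table held 24123 probe sets, of which 124 control probe sets were left out of the tests. Gene names came from the platform annotation: 10069 of the 23999 tested probe sets had 1 gene symbol, 198 had several and 13732 had none here. Of the 10069, 9961 had an Entrez ID in a RefSeq gene table, and 0 symbols changed on updating through it. No gene was named from a probe set with several symbols, and no coordinates were used. Each of the 6765 genes was represented by its probe set with the highest mean over all 20 arrays. Background was the range of tag and tryptophan control probe sets that match no kidney RNA, with an upper end of 2.79. A probe set under that level on all arrays of a group has only a bound there. Its fold is given as the ratio of the brighter group's mean to the mean of, per array, the higher of the lowest signal above background and the probe set's own. Arrays of the brighter group enter as read, so the fold is not a strict bound where some of them lie under background.

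Probe sets were compared with limma 3.58.1 (lmFit and eBayes, without trend) in R 4.3.3, on log2 values as deposited. The main fit had no covariate, since the animals were randomized. Animal numbers were not balanced between groups all the same, with 7 of 10 ND animals and 1 of 10 controls up to 100. A term for animal number was among the alternatives. The threshold was an adjusted p under 0.05 (Benjamini-Hochberg over all 23999 probe sets). Of 31 gene lists written before the data were examined, 30 had at least 5 measured members and were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation, fry and a permutation test of each list's mean level per array stood beside it, and passed 1, 6 and 8 lists against 10 with the preset correlation. The lists were cytokines, chemokines and NF-kB targets; immediate early genes; heat shock; unfolded protein response; hypoxia and glycolysis; oxidative stress; kidney injury; p53 targets; glucocorticoid targets; clock genes; interferon response; complement; coagulation; vasoactive systems; proximal tubule; distal nephron; oxidative phosphorylation; fatty acid oxidation; gluconeogenesis; cholesterol synthesis; cell cycle; extracellular matrix; and markers of neutrophils, macrophages, T and NK cells, B cells, red cells and platelets, endothelium, podocytes, fibroblasts and smooth muscle, and adipose tissue. They share some members. Marker levels in whole tissue are not cell shares.

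Group differences of single measures used two-sided permutation tests with 100000 resamples, or exact enumeration where groups were smaller. Genes named in the text follow a rule set before the data were examined: the 10 largest rises and 10 largest falls among changed genes with a plain symbol, up to 3 members per list with the smallest p, and 14 genes of prior interest. NR3C1, SGK1, KLF15, MRC1, CD14, HBB, CCL5, CCL4, ICAM1, IER5, SLC7A7, FAM107A, FOXO1, TXNIP, AZGP1 and SESN1 fall outside the rule and were chosen after their values were seen. The last 5 come from a second glucocorticoid list, which was itself written before its values were examined.

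The fit was tested on simulated data for all 23999 probe sets with the real means and spreads, 10 arrays against 10. At a 1.41-fold change 38.8% of the changed probe sets were recovered, at 2-fold 83.6% and at 4-fold 100%. The changed probe sets were drawn from those with a mean log2 signal above 4, so these rates do not cover dimmer ones. Of 177 probe sets called, 16 were unchanged ones. The shifted gene list was found and 0 unshifted lists were called. Simulated noise was independent between probe sets, so this does not show how often camera calls lists of correlated genes by chance. In random splits of the real arrays camera called up to 15 lists. Alternatives covered scaling, a filter on dim probe sets, the variance model, array weights, the summary per gene, an animal number term, subsets of animals, the threshold, a minimum fold of 1.2 and leaving out each animal in turn. The alternative for linear intensities was not needed.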

Results

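Kidney RNA of 20 pigs was measured on 1-colour Affymetrix porcine arrays, with 1 array per animal. The 10 control animals had received the surgical preparation and anaesthesia only, and the 10 animals of the neurologic death (ND) group had in addition had a balloon inflated under the dura until ND was established. Both groups were ventilated for 6 h before kidney tissue was frozen. For both groups the labels list 0.9% saline boluses of 2 cc/kg and a mean arterial pressure floor of 35 mmHg. The comparison asked how ND changes gene expression in the kidney before organ recovery. Animals are named by group and number (ND_47, Control_199). Values were log2 signals per probe set, with array medians between 5.09 and 5.35, and the number of arrays limits their precision. All differences below are ND minus control on the log2 scale with 10 animals per group, and adjusted p-values come from limma with Benjamini-Hochberg adjustment over 23999 probe sets unless stated otherwise.

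In the kidneys of ND animals 8 of 15 listed glucocorticoid targets fell, and 6 of 22 members of the cytokine and chemokine list rose. The largest fall was that of CDO1 (cysteine dioxygenase, the first step of cysteine breakdown), whose mean signal was 2.69 ± 0.38 (SD, n = 10) in ND and 8.30 ± 1.02 (SD, n = 10) in controls. Only 4 of the 10 ND arrays read CDO1 above the background level of 2.79. The fall of FKBP5 (a co-chaperone of the glucocorticoid receptor) was -3.32 ± 0.14 (SE), with an adjusted p of 7.21e-12. The largest rise was that of CCL2 (monocyte chemoattractant protein), by 3.84 ± 0.42 (SE), or 14.3-fold, with an adjusted p of 1.77e-05. For each of these 3 genes, the 10 ND values and the 10 control values did not overlap, as for 40 of the 6765 genes measured, where 0.0732 are expected by chance.

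In total 1712 probe sets changed, 913 higher and 799 lower in ND, and by the brightest probe set of each gene 676 of 6765 genes with a single symbol changed (368 higher, 308 lower). At least 2-fold changes were seen for 77 higher and 59 lower genes. Another 863 changed probe sets carried no single gene symbol. The 10 largest rises were those of CCL2, CCL8 (2.31), the urokinase gene PLAU (2.13), the endothelial tight junction gene CLDN5 (2.02), the chemokine CXCL14, EMP3 (1.97), the dendritic cell maturation marker CD83 (1.96), the immediate early transcription factor EGR1 (1.89), PLAC8 (1.80) and the ubiquitin-like gene UBD (1.80), with adjusted p-values between 0.00145 and 0.0402 for those after CCL2. CXCL14 read at background on every control array and above it on 9 ND arrays, a 3.03-fold rise over the background floor with ND arrays taken as read. The 10 largest falls were those of CDO1, FKBP5, PER1 (-2.56), KLF9 (-2.51), ANGPTL4 (-2.47), the mitochondrial arginase ARG2 (-2.39), PDK4 (-2.38), TSC22D3 (-2.26), the deubiquitinase USP2 (-2.19) and SNX8 (-2.08). All 10 ND animals lay on the same side of the control mean for each of these 20 genes. PLAC8 lost its call without ND_01, ND_22, ND_31, ND_92 or ND_198 or Control_02, Control_184, Control_187, Control_190 or Control_199 (adjusted p 0.0509 to 0.0721). B2M, PAFAH1B1, SRSF6 and TYK2 had probe sets called in opposite directions. Among the 20 genes above, a dimmer probe set of PER1 (-0.03), KLF9 (-0.01), ARG2 (-0.20), TSC22D3 (-0.32), CD83 (0.23) and CXCL14 (0.60) moved far less. Among genes named below, TAP1 (-0.04), IRF7 (-0.0007), ATF4 (-0.01), LAPTM5 (-0.05), LCK (-0.03), FCGR3A (-0.02), TMSB10 (-0.05) and PDGFRB (-0.05), for example, had a dimmer probe set that hardly moved.

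The split between rises and falls depended on the scaling. With each array shifted to the same median, 1061 probe sets were higher and 7728 lower, since array medians were 0.09 higher in ND (permutation p = 0.00583) and the median difference over all probe sets moved from -0.03 to -0.12. With quantile normalization 917 were higher and 1198 lower. ND animals carried mostly low animal numbers and controls mostly high ones: 7 of 10 ND animals but 1 of 10 controls were numbered up to 100. That control was Control_02, so within controls a term for this split rests on 1 array. Such a term overlaps largely with group, which lowers the precision of the group difference. With a term for that split 505 probe sets changed (179 higher, 326 lower), and among the 3 ND and 5 control animals numbered from Control_184 upwards 57 changed (19 higher, 38 lower). Of the 83 genes that passed among 124 examined one by one, 25 kept their call with the term: CCL2, CDO1, FKBP5, PER1, KLF9, ANGPTL4, ARG2, PDK4, TSC22D3, USP2, SNX8, BAG3, DDIT3, CA9, ANKRD37, MT1A, AGTR1, NDUFV2, CPT1A, GK, FDFT1, CD163, FABP4, MRC1 and TXNIP. The other 58 lost it.

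Glucocorticoid targets fell, with the lowest median of the 30 lists tested. Of 15 measured members, 8 fell, 1 rose and 6 did not pass, and adjusted over the list alone 10 fell and 1 rose. Their median difference was -1.44 (camera adjusted p = 1.34e-08), and the call held with an estimated correlation (adjusted p = 0.00316), the only list for which it did. Beside FKBP5, the members that fell were TSC22D3 (encoding the anti-inflammatory protein GILZ; -2.26 ± 0.14, SE), the clock gene PER1, the transcription factors KLF9 and KLF15 (-1.44), the lipoprotein lipase inhibitor ANGPTL4, the pyruvate dehydrogenase kinase PDK4 and the kinase SGK1 (-1.46), a regulator of sodium transport. NR3C1, the glucocorticoid receptor gene itself, rose by 0.85 ± 0.20 (SE), with an adjusted p of 0.0124. The fall was present among the animals numbered from Control_184 upwards, where FKBP5 (adjusted p = 0.00256) and TSC22D3 (-2.46, adjusted p = 0.0259) passed and the list kept its call (camera adjusted p = 0.000158; 5.59e-10 to 0.00316 over the alternatives fixed beforehand).

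**Figure D1:**
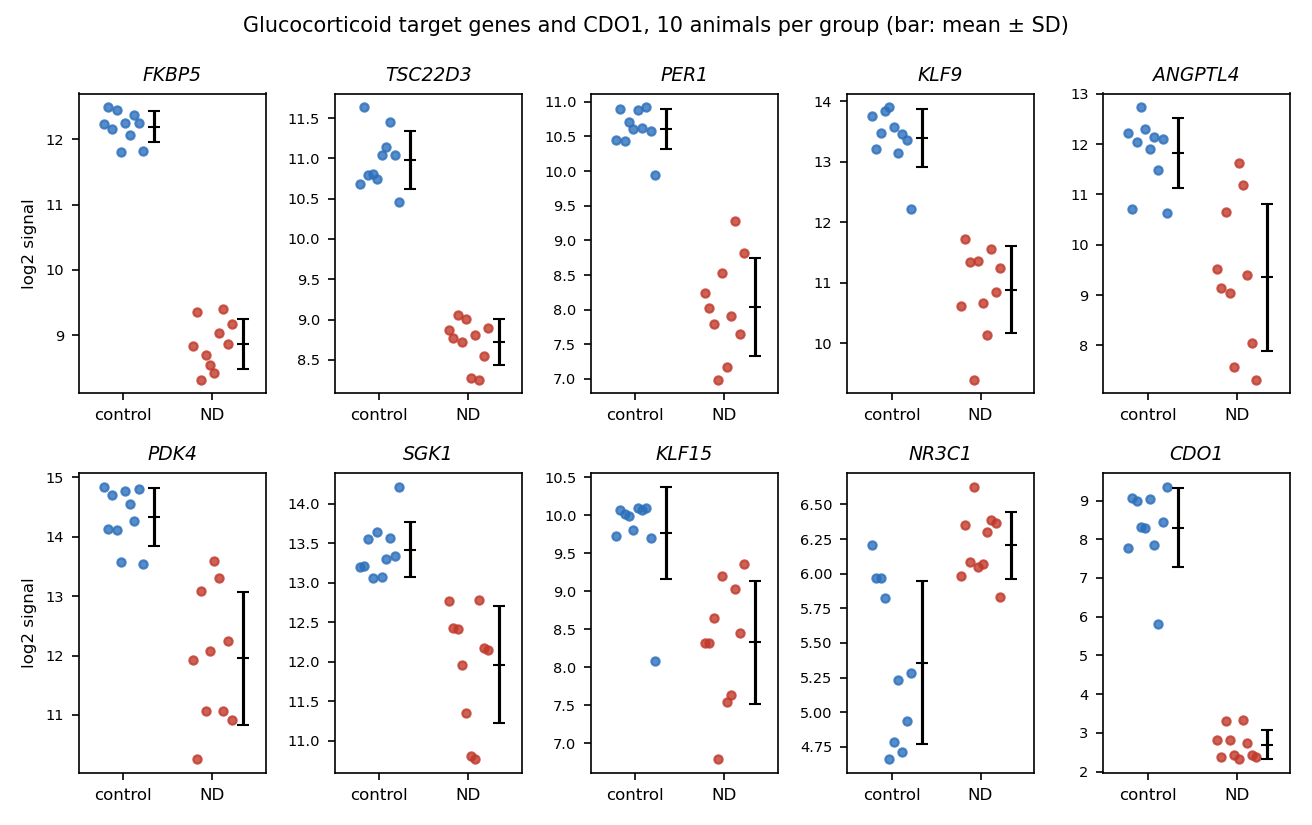
Log2 signal of 10 genes in each of 10 control (blue) and 10 ND (red) animals, with the mean ± SD as a bar beside the points and a separate vertical scale per gene. FKBP5, at 12.2 in controls and 8.87 in ND, shows no overlap between groups, while NR3C1 is the 1 gene shown that was higher in ND.

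Of 22 measured cytokine, chemokine and NF-kB target genes 6 rose, none fell and 16 did not pass (7 rose adjusted over the list alone): CCL2, CCL5 (1.43), CCL4 (1.25), the leukocyte adhesion molecules VCAM1 (1.70 ± 0.31, SE) and ICAM1 (0.96), and the transcription factor IRF1 (1.04). The list median was 0.47 (camera adjusted p = 3.85e-05), and the call was lost with an estimated correlation (adjusted p = 0.549). IL6 (0.42, adjusted p = 0.467) did not pass and read at background on all controls. TNF (0.08, adjusted p = 0.281) did not pass and read at background on all arrays of both groups. CXCL8 did not pass either (0.38, adjusted p = 0.431, and 0.04 without ND_47). IL6 rose above background in 1 ND animal, number 47, whose mean level of the list was 7.47 against 5.38 to 6.06 in the other ND animals. Without ND_47 the list median was 0.13, and without ND_47 and ND_92 the call remained (camera adjusted p = 0.000786), and among animals numbered from Control_184 upwards the median was 0.01 and the call was lost (camera adjusted p = 0.184; 2.91e-06 to 0.549 over the alternatives fixed beforehand).

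Of 20 interferon response genes 3 rose, none fell and 17 did not pass (5 rose adjusted over the list alone): GBP1 (1.72), the peptide transporter TAP1 (1.12 ± 0.19, SE) and the transcription factor IRF7 (1.08). The list median was 0.83 (camera adjusted p = 2.45e-05), and the estimated correlation gave an adjusted p of 0.549. GBP1 lost its call without ND_01, ND_22, ND_47 or ND_92 or Control_134, Control_155, Control_184, Control_187, Control_190 or Control_197 (adjusted p 0.0512 to 0.0651). Among immediate early genes, EGR1, FOS (1.72), IER2 (0.79) and IER5 (0.77) rose and 14 members did not pass, and the list did not either (camera adjusted p = 0.369). IER5 lost its call without ND_86, ND_92 or ND_100 or Control_134, Control_156, Control_157 or Control_190 (adjusted p 0.0503 to 0.0664). In the complement list CD55 (1.28), which restrains complement activation, and C3 (0.79) rose, 19 of 21 did not pass, C1QC was at 0.72 (adjusted p = 0.0731), and the list missed the threshold (camera adjusted p = 0.0707), which it passed with each array shifted to the same median (0.0242) and with gene means (0.0477), but not with an estimated correlation (adjusted p = 0.568). PLAU was the 1 coagulation and fibrinolysis gene of 19 that passed. In that list FGB (fibrinogen beta chain) differed by -1.50 (adjusted p = 0.0528) and SERPINE2 by 1.04 (adjusted p = 0.0630), and the camera adjusted p was 0.767. Adjusted over the list alone, 4 immediate early genes and 3 complement genes rose, and 2 coagulation genes rose and 1 fell.

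**Figure D2:**
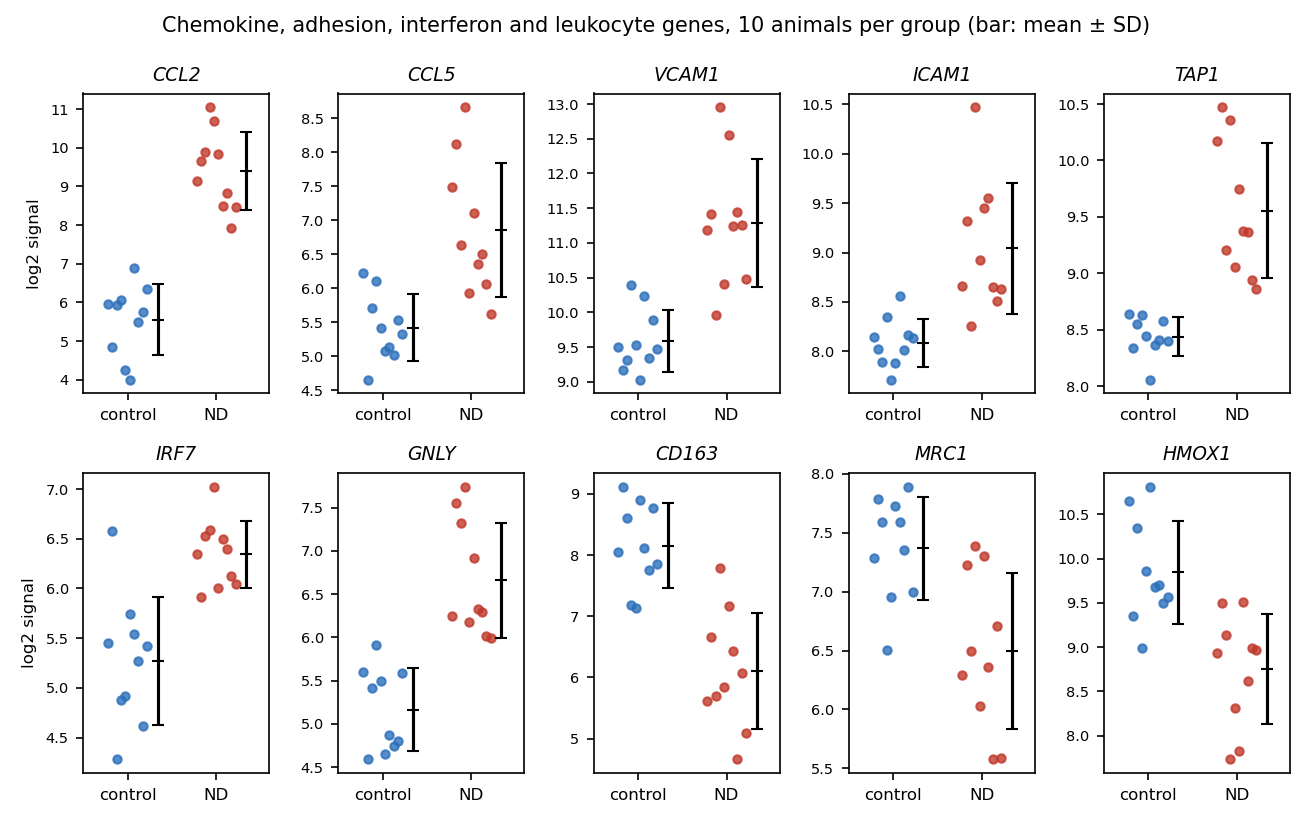
Log2 signal of 10 genes in each of 10 control (blue) and 10 ND (red) animals, with the mean ± SD as a bar beside the points and a separate vertical scale per gene. CCL2 averaged 9.40 in ND and 5.56 in controls with no overlap, and CD163, at 6.10 and 8.15, shows a difference in the opposite direction.

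Leukocyte markers were mixed. Of 20 monocyte and macrophage markers 5 rose and 3 fell (12 rose and 6 fell adjusted over the list alone). LAPTM5 (1.11 ± 0.21, SE) and the protease CTSS (0.85 ± 0.16, SE) were among those that rose. The haemoglobin scavenger receptor CD163 fell by 2.04 on the log2 scale (± 0.36, SE; adjusted p = 0.00194). The mannose receptor MRC1 (-0.87, adjusted p = 0.0366) and the lipopolysaccharide co-receptor CD14 (-0.54, adjusted p = 0.0449) fell as well, with calls that depended on single animals. MRC1 lost its call without ND_01, ND_86, ND_100 or ND_198 or Control_134, Control_155, Control_184, Control_187, Control_190 or Control_197 (adjusted p 0.0527 to 0.0671), and CD14 without ND_22, ND_31, ND_86, ND_92, ND_193, ND_194 or ND_198 or Control_155, Control_156, Control_187, Control_190 or Control_197 (adjusted p 0.0511 to 0.0820). The list passed (camera adjusted p = 0.0192) but not with an estimated correlation (adjusted p = 0.601), and without ND_47 its adjusted p was 0.0505 (0.00220 to 0.722 over the alternatives fixed beforehand). The permutation test of its mean level did not pass (adjusted p = 0.224). Of 17 T cell and NK cell markers 5 rose (9 adjusted over the list alone), among them the cytotoxic granule protein GNLY (1.49 ± 0.25, SE) and the T cell kinase LCK (1.13). CD3E read at background on all control arrays and above it on 5 ND arrays. Over the background floor its rise was 1.25-fold with ND arrays taken as read, which is not a strict bound. The list passed (camera adjusted p = 0.00952), and the adjusted p was 0.549 with an estimated correlation. With the animal number term neither leukocyte list passed (0.486 for macrophages, 0.0582 for T and NK cells). Of 13 neutrophil markers FCGR3A (0.98) and ITGB2 (0.83) rose, both of which other leukocytes also express, TREM1 was at background on all arrays, and 2 rose adjusted over the list alone (camera adjusted p = 0.982). ITGB2 lost its call without ND_01, Control_157 or Control_187 (adjusted p 0.05001 to 0.0526).

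Few markers of other cell types passed. None of 7 B cell and plasma cell markers passed (camera adjusted p = 0.850), with JCHAIN at 1.13 (adjusted p = 0.108), TNFRSF17 at -0.73 (adjusted p = 0.195) and CD38 at background on all arrays. None of 9 red cell and platelet markers passed (camera adjusted p = 0.982), with HBB at -0.21 (95% interval -0.51 to 0.09), ITGB3 at 0.86 (adjusted p = 0.153) and HBE1 and PPBP at background on all arrays. CLDN5 was the 1 endothelial marker of 17 that passed, while TIE1 (0.54, adjusted p = 0.0933) and EGFL7 (0.32, adjusted p = 0.155) did not, and the list had a camera adjusted p of 0.136. PDGFRB (0.65) rose among 17 fibroblast, mesangial and smooth muscle markers, SYNM (-0.75, adjusted p = 0.0721) did not pass, and the list did not pass (camera adjusted p = 0.369). PDGFRB lost its call without ND_01, ND_22, ND_86 or ND_92 or Control_02, Control_134, Control_157, Control_184 or Control_190 (adjusted p 0.0510 to 0.0661). The fat cell lipid carrier FABP4 (-0.89) fell among 14 adipose and peri-renal markers (camera adjusted p = 0.273), where CHGA was at -0.05 (adjusted p = 0.126). UPK3A, at background on all controls and above it on 4 ND arrays, differed by 0.46 (adjusted p = 0.208). With 4 measured members the podocyte list was not tested, and its genes TCF21 (0.28, adjusted p = 0.211), WT1 (0.09, adjusted p = 0.469) and LAMB2 (0.13, adjusted p = 0.504) did not pass. Adjusted over the list alone, 1 endothelial marker rose, 3 fibroblast and smooth muscle markers rose and 1 fell, 1 adipose marker fell, and none of the B cell or red cell markers passed.

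Few genes of energy metabolism passed. Of 33 members of the mitochondrial oxidative phosphorylation and biogenesis list 2 fell, the complex I subunit NDUFV2 (-0.28 ± 0.06, SE) and the citric acid cycle enzyme OGDH (-0.43), as did 2 adjusted over the list alone. NDUFS1 (-0.27, adjusted p = 0.0581) and the biogenesis regulator PPARGC1A (-0.41, adjusted p = 0.0916) did not pass. The list median was -0.14 (camera adjusted p = 0.000329; adjusted p = 0.549 with an estimated correlation). In fatty acid oxidation and ketogenesis 3 of 26 fell, by either adjustment: PDK4, the carnitine palmitoyltransferase CPT1A (-0.88 ± 0.19, SE) and the carnitine acetyltransferase CRAT (-0.36), with a camera adjusted p of 0.00435 (adjusted p = 0.549 with an estimated correlation). In gluconeogenesis and ammoniagenesis PCK1 (-0.66), the rate-limiting enzyme of gluconeogenesis, and the glucose-6-phosphate transporter SLC37A4 (-0.86) fell, the glycerol kinase GK rose (0.97), and 9 of 12 did not pass. Adjusted over the list alone 5 fell and 1 rose, and the camera adjusted p was 0.0176 (adjusted p = 0.549 with an estimated correlation). With the animal number term none of the 3 lists passed (camera adjusted p = 0.121, 0.169 and 0.437), and without ND_47 and ND_92 the last 2 did not (0.0922 and 0.0538). GK lost its call without ND_01, ND_31, ND_86, ND_92, ND_100 or ND_194 or Control_02, Control_134, Control_155, Control_156, Control_157 or Control_184 (adjusted p 0.0510 to 0.0624).

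Of 20 proximal tubule genes 4 fell (4 fell and 1 rose adjusted over the list alone): the glucose transporter SLC2A2 (-1.82 ± 0.41, SE), the amino acid transporters SLC7A9 (-1.13) and SLC7A7 (-0.78), and the transcription factor HNF4A (-0.84), whose group values did not overlap. The list as a whole did not pass (camera adjusted p = 0.336). None of 10 loop of Henle, distal tubule and collecting duct genes passed over all probe sets, and 2 fell adjusted over the list alone. KCNJ1 (-0.50, adjusted p = 0.0758), SCNN1B (-0.49, adjusted p = 0.0876) and AQP3 (-0.54, adjusted p = 0.106) had the smallest p-values there, and the camera adjusted p was 0.443. Among 22 genes of vasoactive and hormone systems the angiotensin II receptor AGTR1 (-1.01 ± 0.18, SE) and CYP27B1 (-1.43), which activates vitamin D, fell, as did 2 adjusted over the list alone. ACE was at -0.16 (adjusted p = 0.172), and the list did not pass (camera adjusted p = 0.921). SLC7A7 lost its call without ND_92 or ND_100 or Control_02, Control_155, Control_156 or Control_157 (adjusted p 0.0522 to 0.0590), and CYP27B1 without ND_01, ND_47 or ND_92 or Control_02, Control_184 or Control_199 (adjusted p 0.0505 to 0.0575).

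In the stress pathways single genes passed and no list did in the main comparison. The co-chaperone BAG3 fell (-1.26 ± 0.16, SE; adjusted p = 7.89e-05) while 15 of 16 heat shock genes did not pass, HSP90AB1 (0.22, adjusted p = 0.225) and SERPINH1 (0.61, adjusted p = 0.235) among them, with a camera adjusted p of 0.499. In the unfolded protein and amino acid stress list DDIT3 (1.19), the asparagine synthetase ASNS (1.25) and ATF4 (0.67) rose, and 14 of 17 did not pass (camera adjusted p = 0.507). In the hypoxia and glycolysis list the carbonic anhydrase CA9 (-1.23) and ADM (-0.83) fell and ANKRD37 (1.07) rose, and 18 of 21 did not pass (camera adjusted p = 0.318). The haem oxygenase HMOX1 (-1.09) and the metallothionein MT1A (-1.48) fell among 23 oxidative stress and metal genes, TXN was at 0.21 (adjusted p = 0.0535), and the list did not pass (camera adjusted p = 0.982). BAX (0.59) rose and CASP8 (0.85, adjusted p = 0.0556) and GADD45A (-0.91, adjusted p = 0.123) did not pass among 15 genes of p53 targets and apoptosis (camera adjusted p = 0.552). Without ND_92 the adjusted p of BAX was 0.0501. ARNTL (-0.58) and PER1 fell among 7 clock genes, CRY2 (-0.64, adjusted p = 0.0766) did not pass, and the list missed the threshold (camera adjusted p = 0.0517). The clock list passed with quantile normalization (0.0193), brighter probe sets only (0.0104), gene means (0.0477), fry (0.0139) and the permutation test of its mean level (0.0127), but not with the animal number term (0.269) or an estimated correlation (adjusted p = 0.549). Adjusted over the list alone, 1 heat shock gene fell, 3 unfolded protein genes rose, 1 hypoxia gene rose and 2 fell, 2 oxidative stress genes rose and 2 fell, 2 p53 and apoptosis genes rose and 3 clock genes fell.

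Single genes passed among injury, matrix and cholesterol genes. Kidney injury and repair markers passed as a list (camera adjusted p = 0.00435; adjusted p = 0.549 with an estimated correlation). Of 19 members TMSB10 (0.82), ANXA1 (0.66) and S100A10 (0.29) rose, and 6 rose and 1 fell adjusted over the list alone. ANXA1 lost its call without ND_92, Control_184 or Control_190 (adjusted p 0.0516 to 0.0538), and S100A10 without ND_01, ND_22, ND_47, ND_92, ND_100 or ND_194 or Control_155, Control_156, Control_184, Control_190, Control_197 or Control_199 (adjusted p 0.0526 to 0.0780). The extracellular matrix and TGF-beta list passed (camera adjusted p = 0.00952; adjusted p = 0.549 with an estimated correlation) with 1 of 24 members, THBS2 (0.93), past the threshold. TGFB1 was at 0.97 (adjusted p = 0.0514) and LUM at 1.33 (adjusted p = 0.0618). Adjusted over the list alone 3 rose. The injury and matrix lists lost their calls with the animal number term (camera adjusted p = 0.121 and 0.109) and without ND_47 and ND_92 (0.0538 and 0.0922). Neither passed the permutation test of its mean level (adjusted p = 0.125 and 0.0995). Without ND_92 the adjusted p of THBS2 was 0.0508. Of 13 cholesterol synthesis genes FDFT1 (0.59) and ACAT2 (0.60) rose, as did 2 adjusted over the list alone, while HMGCS1 was at 0.50 (adjusted p = 0.127; camera adjusted p = 0.0525, 0.0283 with the animal number term and 0.549 as an adjusted p with an estimated correlation), and ACAT2 lost its call without ND_31, ND_47, ND_86, ND_100 or ND_193 or Control_02, Control_134, Control_155, Control_184, Control_190, Control_197 or Control_199 (adjusted p 0.0504 to 0.0718). None of 21 cell cycle genes passed by either adjustment, with CDK2 at 0.32 (adjusted p = 0.0510), CDC20 at -0.04 (adjusted p = 0.174) and PLK1 at background on all arrays, and the camera adjusted p was 0.369. EPO, at background on all controls and above it in 3 ND animals, differed by 0.56 (adjusted p = 0.247). HAVCR1, LCN2, HSPA1A, AQP2 and UMOD were not analysed here.

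**Figure D3:**
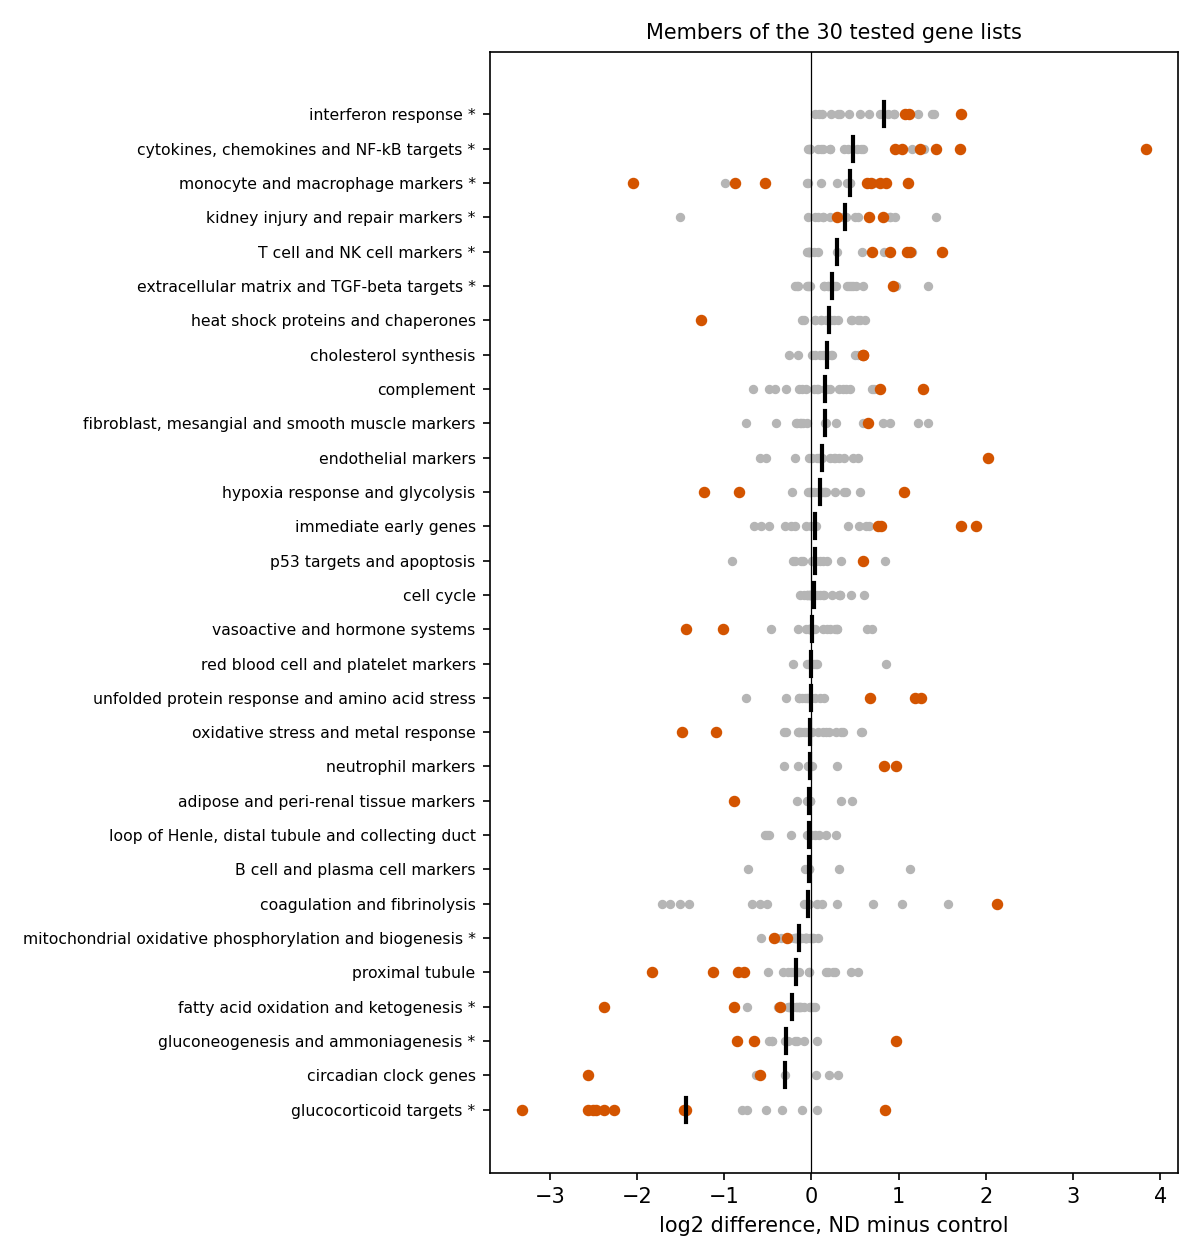
Log2 difference (ND minus control) of each measured member of the 30 tested gene lists; orange points passed an adjusted p of 0.05 over all probe sets, grey points did not, black bars are list medians and a star marks a list past the camera threshold. The glucocorticoid list lies apart with a median of -1.44, and the next lowest median is -0.31 for clock genes.

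The median, mean and camera direction of a list differed in sign for 6 lists that did not pass. For the unfolded protein list the median was -0.01 and the mean 0.10 (camera up), for the oxidative stress list -0.02 and -0.05 (camera up), and for the vasoactive list 0.00 and -0.02 (camera down). For neutrophil markers the median was -0.02 and the mean 0.11 (camera down), for B cell markers -0.03 and 0.08 (camera down), and for red cell and platelet markers -0.00 and 0.08 (camera up). The camera direction turned for the coagulation and red cell lists with each array shifted to the same median, and for the vasoactive, neutrophil and B cell lists with quantile normalization, all without a call.

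The groups separated along the main axes of variation. Component 1 held 26.2% of the variance and differed by 45.1 between groups (permutation test, two-sided, adjusted p = 0.00012), with ND_47 at 99.4 and ND_92 at 47.7 the farthest from the controls. Component 2 (13.3%) differed by 3.53 (adjusted p = 0.737). Component 3 (11.4%) differed by 27.2 (adjusted p = 0.00342), and by 7.46 without ND_47 and 12.6 without Control_156, both no longer past the threshold. Among the animals numbered from Control_184 upwards component 1 differed by 52.4 (exact permutation test, adjusted p = 0.0536). With 56 arrangements the smallest unadjusted p is 0.0179, which adjusts to 0.0536 when no other component has a small p. The distance of an array from the mean of its own group was 0.42 ± 0.12 (SD, n = 10) in ND and 0.36 ± 0.05 (SD, n = 10) in controls (permutation p = 0.181). The difference between groups, 0.0532, ranged from 0.0146 to 0.0681 when each animal was left out in turn. Signs of RNA quality (the 3' minus 5' signal of GAPDH, actin and EF1A, and 28S rRNA) did not differ past the threshold (permutation adjusted p between 0.270 and 0.763). The hybridisation spike-ins averaged 11.63 in ND and 11.88 in controls, a difference of -0.25 (permutation adjusted p = 0.0332). These control probe sets do not measure kidney RNA, so the arrays of the 2 groups differed technically. Whether that difference bears on the calls was not tested.

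**Figure D4:**
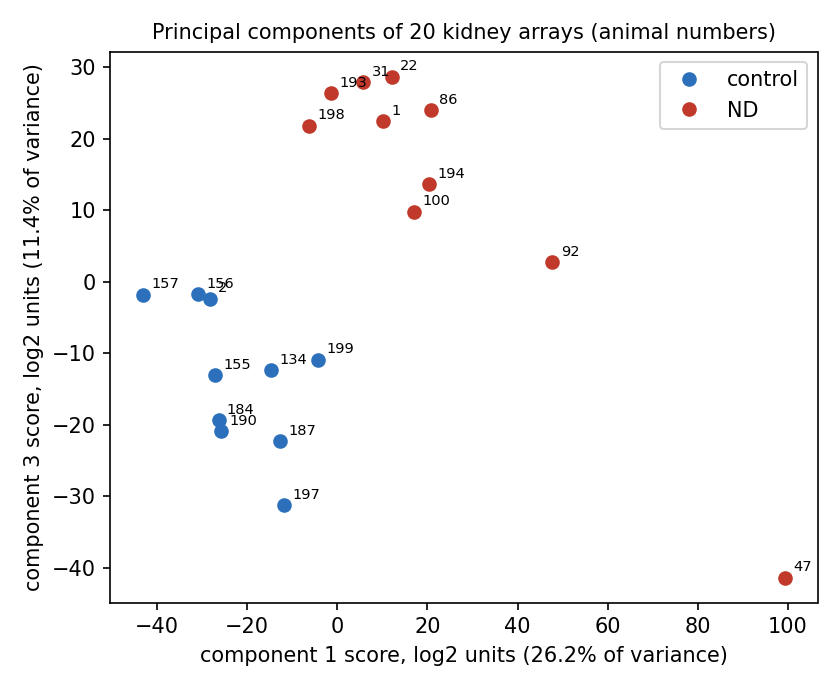
Scores of the 20 arrays on components 1 and 3, in log2 units, with animal numbers beside the points (blue, control; red, ND). Most ND arrays lie to the upper right of the control arrays, but ND_198 scored lower on component 1 (-6.30) than Control_199 (-4.35), and ND_47 has the highest score on component 1 (99.4) and the lowest on component 3 (-41.4).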

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

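In this part, the tests of time of day, of residual blood (HBB) and of whether the cytokine list stays past its threshold or keeps its mean level were chosen after the results they bear on were seen, as were the alternatives without ND_47 and ND_92 and without the control arrays lacking a spike-in signal.

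In 36 of 342 groups of 10 values, 1 array lay apart from the rest by more than Dixon's 95% critical value, where chance gives 17.1. In 18 of the 36 that array was ND_47. Its distance from the other ND arrays was 0.723, its score was 99.4 on component 1 and -41.4 on component 3. Its mean level was 7.47 for the cytokine list, 10.5 for kidney injury markers, 8.60 for glucocorticoid targets, 9.35 for proximal tubule genes and 10.9 for gluconeogenesis. ND_47 had the highest ND signal of IL6 (6.41), CXCL8 (6.34), CLDN5 (9.62), HSP90AB1 (13.9), SERPINH1 (11.16), ASNS (11.5), ANXA1 (10.98), CASP8 (7.40) and PDGFRB (12.04) and the lowest of AGTR1 (8.11). Control_199 was lowest among controls for PER1 (9.94), KLF9 (12.2), KLF15 (8.09), ARNTL (7.54) and SLC37A4 (12.1) and highest for SGK1 (14.2) and EPO (2.36, under background). The other such arrays were Control_134 for UBD (5.39) and KCNJ1 (11.3), Control_190 for CDO1 (5.81), Control_184 for TAP1 (8.06) and HNF4A (13.1), Control_157 for CD55 (2.82), ND_86 for ACE (3.166), Control_199 for PPBP (2.454), Control_156 for UPK3A (2.553), ND_31 for OGDH (9.14) and ND_198 for NDUFS1 (11.4).

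The 20 arrays were split into 10 and 10 in 100 ways, the real split included. Only the real split gave as many as 1712 changed probe sets (highest other 1) and 676 changed genes (highest other 1). This argues against chance for both counts. The other splits mixed ND with control animals, so they do not bear on the animal number series. For the number of gene lists past the camera threshold, 16 of the 100 splits gave at least the real 10, and the highest other gave 15, so chance was not excluded for that number. Camera at the preset correlation thus called lists in random splits as well, and such a call alone does not exclude chance for a single list.

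The fall of glucocorticoid targets (list median -1.44) was set against technical explanations. Without ND_47 and ND_92 the median was -1.15, and among animals numbered from Control_184 upwards -1.13, both of which argue against outlying arrays or the animal number series as the whole cause. A difference in time of day stays open: the largest 95% bound among clock genes outside the list was 1.09 in size, under that of the list median. Of these genes ARNTL fell, while CRY2 (-0.64), NFIL3 (-0.31), RORA (0.31), BHLHE40 (0.20) and DBP (0.05) did not pass. But the clock list, which shares PER1, passed in several alternatives (0.0193 with quantile normalization). The clock list did not pass in the main fit (camera adjusted p = 0.0517), with an estimated correlation (0.549) or with the animal number term. As a hypothesis, lower glucocorticoid receptor activity may account for the fall: a second list of receptor-induced genes was lower in ND in the 1-sided camera test (p = 0.0305), but not in the 2-sided one (p = 0.0610), and its members above background had a median of 0.00.

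The cytokine list median of 0.47 was 0.13 without ND_47, 0.50 without ND_92, 0.125 without both and 0.00526 among animals numbered from Control_184 upwards, the last 2 under the bound of 0.2 set beforehand, as outlying arrays and the animal number series would each give for the median. The difference in the mean level of the list was 0.72 over all arrays, 0.50 (0.4996) without both arrays (permutation p = 5e-05), which argues against these arrays as the whole cause of that difference, and 0.262 from Control_184 upwards (exact permutation p = 0.0536), which leaves the animal number series open. The list call likewise held without both arrays (camera adjusted p = 0.000786; 2.91e-06 to 0.549 over the alternatives fixed beforehand) and with the animal number term (0.0175), but not from Control_184 upwards (0.184). HBB, whose upper 95% bound was 0.0925, argues against more red cell RNA in ND kidneys. As 1 red cell transcript it cannot tell whether they held more blood leukocytes. The median rise of the 10 T cell and macrophage genes called higher was 0.88, a value raised by choosing called genes. The medians of the full lists over all arrays, 0.30 for T and NK cells and 0.44 for macrophages, also lay above the bound. Among animals numbered from Control_184 upwards the median for T and NK cells was 0.04, under the bound. An effect of ND on inflammation stays open as the biological explanation.

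The dap spike-in RNA, added before labelling and outside the comparisons above, read 7.42 on average in ND, but 2.44 and 2.72 on Control_02 and Control_134, near background. Without these control arrays 1612 probe sets changed against 1712, 513 of the 676 changed genes kept their call and 17 of the 83 genes examined one by one lost it, which argues against them as the source of most calls but not of each. No biological explanation was tested for this pattern.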

How the results depend on the processing

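The alternatives without ND_47 and ND_92 and without Control_02 and Control_134 were chosen after the data were seen, and the others before. Of 124 genes examined 83 passed, 0 of these reversed in any setting and 66 kept their call whichever animal was left out, but 58 lost it with the animal number term and 79 among animals numbered from Control_184 upwards. That subset held 3 ND and 5 control animals, so a lost call there does not by itself speak for the animal number series. Differences shrank there as well. Among members called higher over all arrays, the median difference went from 1.09 to 0.32 for T and NK cell markers. For the cytokine list it went from 1.34 to 0.90, and the median of all glucocorticoid targets from -1.44 to -1.13. Members chosen as called over all arrays can shrink in any subset, so the animal number series stays open for these rises. The glucocorticoid list kept its call in all 31 alternatives fixed beforehand. The groups share no animal numbers. No paired analysis was possible because of this. The alternative for linear values was not run, since the values were log2. Signal near background limits IL6, TNF, EPO, CD3E, CXCL14 and UPK3A. Unless stated, values for lists are camera adjusted p-values, and the cause was not tested.

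With each array shifted to the same median, 8789 probe sets and 2048 genes changed, because a shift common to most probe sets was added; gluconeogenesis was lost (0.0611), and TNF (-0.0078), coagulation (0.862) and red cell markers (0.674) reversed without a call. Gained were complement with that shift (0.0242) and with gene means (0.0477), and clock genes with quantile normalization (0.0193), brighter probe sets (0.0104), gene means (0.0477) and fry (0.0139), but neither list with an estimated correlation (0.568 and 0.549). Other reversals without a call were vasoactive (0.775), neutrophil (0.695) and B cell lists (0.771) with quantile normalization, oxidative stress (0.971) and component 2 (-1.99) with only brighter probe sets, red cell markers with trend and robust fitting (0.892), neutrophil markers with array weights (0.993), oxidative stress with gene means (0.743) and with fry (0.817), and red cell markers without Control_02 and Control_134 (0.974).

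With the animal number term 505 probe sets, 188 genes, 25 named genes and 4 lists passed: glucocorticoid, cytokine, interferon and, gained, cholesterol synthesis (0.0283; also 0.0310 without ND_47 and ND_92, but 0.549 with an estimated correlation). Lost were kidney injury (0.121), oxidative phosphorylation (0.121), fatty acid oxidation (0.169), gluconeogenesis (0.437), extracellular matrix (0.109), macrophage (0.486) and T cell lists (0.0582), and reversed without a call oxidative stress, p53 and proximal tubule (each 0.949) and neutrophil lists (0.975). Among animals numbered from Control_184 upwards, with fewer animals, 57 probe sets, 22 genes, 4 named genes and 2 lists passed. Lost there were cytokines (0.184), kidney injury (0.486), oxidative phosphorylation (0.255), fatty acid oxidation (0.324), gluconeogenesis (0.600), extracellular matrix (0.1002), macrophages (0.722), T cells (0.151) and component 3 (0.566). Component 1 (52.4) did not pass there (exact permutation test, adjusted p = 0.0536). With 56 arrangements the smallest unadjusted p is 0.0179, which adjusts to 0.0536 when no other component has a small p. The spread differed (0.0560, exact permutation p = 0.0357). Reversed without a call were TGFB1 (-0.031), IL6 (-0.0189), CXCL8 (-0.1012), SERPINH1 (-0.0629), HMGCS1 (-0.0255), LAMB2 (-0.1079), component 2 (-0.915), immediate early, p53, red cell and endothelial lists (each 0.944), heat shock (0.722), unfolded protein (0.876) and proximal tubule (0.184).

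Stricter thresholds gave fewer calls by construction: 619 probe sets and 245 genes at an adjusted p under 0.01, with gluconeogenesis (0.0176) and macrophages (0.0192) lost, and 219 probe sets, 78 genes and 29 named genes with a minimum fold of 1.2. With an estimated correlation 1 list passed, at 0.549 for the cytokine, kidney injury, interferon, oxidative phosphorylation, fatty acid oxidation, gluconeogenesis, extracellular matrix and T cell lists and 0.601 for macrophages. With fry 6 passed, and cytokines (0.0556), kidney injury (0.114), fatty acid oxidation (0.109), extracellular matrix (0.114) and macrophages (0.137) did not. The permutation test of the mean level passed 8 lists, but not kidney injury (0.125), extracellular matrix (0.0995) or macrophages (0.224). Without ND_47 and ND_92, 6 lists passed, and kidney injury (0.0538), fatty acid oxidation (0.0922), gluconeogenesis (0.0538), extracellular matrix (0.0922) and macrophages (0.0922) did not, while heat shock (0.915), proximal tubule (0.875) and neutrophil lists (0.915), component 2 (-23.9, now past the threshold at a permutation adjusted p of 0.0430) and component 3 (-0.106) reversed; components were recomputed from the arrays left.

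Leaving out each animal in turn gave 1295 to 2303 probe sets, 513 to 766 genes and 9 to 12 lists. Lists that passed without some animals were clock genes (0.0199 to 0.103), complement (0.0223 to 0.152) and cholesterol synthesis (0.0158 to 0.120). The macrophage list ranged from 0.00482 to 0.0505 (lost without ND_47), component 2 from -26.1 (without Control_156, past the threshold) to 17.8, component 3 from 7.46 to 29.6 (lost without ND_47, 7.46, and without Control_156, 12.6), and, without a call, oxidative stress from 0.751 to 0.995, vasoactive from 0.797 to 0.988, neutrophil from 0.875 to 0.998 and red cell lists from 0.786 to 0.994. The vasoactive list turned direction without ND_31 (0.988).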

Other observations

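In this part, the second list was written before its values were examined and the correlation test before its result was seen. FAM107A, FOXO1, TXNIP, AZGP1 and SESN1 were singled out after their values were seen.

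A further 5 genes known to be induced through the glucocorticoid receptor fell in ND. They were FAM107A (-1.30 ± 0.25, SE), the insulin-regulated transcription factor FOXO1 (-0.62), the thioredoxin inhibitor TXNIP (-0.87), AZGP1 (-0.86) and the stress sensor SESN1 (-0.50), with limma adjusted p-values between 0.00336 and 0.0480 and 10 animals per group. Of 42 genes on that second list 17 were measured, 5 fell, 0 rose, and the median was -0.07 (0.00 over the 14 members above background), and the other members did not pass. Its 1-sided camera p was 0.0305, and 0.0376 with an estimated correlation. SESN1 lost its call in 16 of the 20 fits that left out an animal (all but ND_198 and Control_187, Control_197 and Control_199; adjusted p 0.0507 to 0.0850) and AZGP1 without ND_92, Control_02, Control_157 or Control_190 (adjusted p 0.0504 to 0.0551).

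A hypothesis was that less glucocorticoid restraint may go with more inflammation in the same animal. Within the 10 ND animals the mean levels of the glucocorticoid and cytokine lists correlated with r = -0.828 (permutation p = 0.0698, adjusted p = 0.140 over 2 groups) and rho = -0.16 (permutation p = 0.658, adjusted p = 0.658). Without ND_47 and ND_31, the farthest from the median, r was 0.35, so the relation rested on those animals, mainly ND_47. In controls r was 0.31 (permutation p = 0.394) and rho 0.24 (permutation p = 0.513). The p missed the bound set beforehand, which would count against the hypothesis. It was left open instead, because with 10 animals and 1 of them setting r, neither the coefficient nor its p decides.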
